A study of Arabidopsis thaliana with 4 samples.

How the data were processed

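Gene expression was measured in 7-d-old wild-type Arabidopsis thaliana seedlings of the Ler accession, grown under low light, on 4 Affymetrix ATH1 arrays, an oligonucleotide array for Arabidopsis in which several short probes form a probe set for each transcript. The 4 groups, taken from the sample labels, crossed RNA fraction (total RNA or RNA from large polysomes) with condition (non-stressed control or 12 h of hypoxia), with 1 array in each group. The description of the large-polysome control gives 12 h and that of the total RNA control gives no time, so hypoxia over control in total RNA, large-polysome over total RNA in control and the change of association may include a difference in sampling time. Large polysomes are mRNAs carrying many ribosomes, so the ratio of large-polysome to total signal describes the share of an mRNA found on large polysomes compared with the average mRNA on the same arrays. It is not a direct measure of translation.

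The deposited values were linear probe set intensities, 1 for each of 22810 probe sets on each array. The software that summarised the probes, and its background correction, are not given in the sources used here. On every array the mean intensity between the 2nd and the 98th percentile of the deposited values was 500, so the authors' values had been scaled to a common target, as far as the values show. Per the file headers, all 4 arrays were of the same chip lot, were washed and stained with the same protocol at the same station and were hybridised on the same day; the array of total RNA in hypoxia had been scanned 2 times and the others 1 time. Because each array was set to the same mean, every value below is relative to the average signal of its array. A change in the overall amount of mRNA, or in the share of it on large polysomes, cannot be seen.

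The probe sets were named from the platform annotation supplied with the values, with symbols updated through the Entrez identifier to the RefSeq annotation of assembly TAIR10.1, which was used for names and for the organelle of a gene only. Of the 22746 probe sets that were not controls, 13513 had 1 gene, 503 had several and 8730 were not listed and are unnamed here; 13436 of the 1-gene probe sets matched a RefSeq gene and 77 did not and kept the platform's name. Unnamed probe sets were brighter, with a median intensity of 317 in total RNA of control seedlings against 166 for named ones. A gene with several probe sets took the probe set with the highest mean over the arrays, which left 13356 genes. ADH1, PDC1, SUS1, SUS4 and HB1, which had been chosen in advance to be reported in every array, had no named probe set and could not be given.

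Intensities were rescaled to the same mean between the 2nd and 98th percentiles of the non-control probe sets, with factors from 0.999 to 1.001. The floor was the highest over the arrays of the 40th percentile, an intensity of 139. Values below it were set to it before log2 was taken. A gene below the floor on both arrays of a ratio had no ratio, and a gene below it on 1 side had a bound, which entered counts and list medians at its bound. Between 54.7% and 59.98% of non-control probe sets were above the floor on an array, 5842 genes were above it on all 4 arrays and 5460 on none.

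There were 5 comparisons. They were hypoxia over control in total RNA, the same in large-polysome RNA, large-polysome over total RNA in control, the same in hypoxia, and the change of association, which is the log2 difference between the last 2 and was computed only for genes above the floor on all 4 arrays. With 1 array per group the spread between samples cannot be estimated, so no p-value was computed, no difference has a replicate check, and a threshold of 2-fold served to count genes. The number of arrays limits the precision. As a measure of probe error within an array, pairs of probe sets of the same gene differed in their log2 ratio by a median of 0.33 in total RNA (62 genes), 0.37 in large-polysome RNA (30 genes), 0.45 and 0.51 for the fraction ratios in control and hypoxia (32 and 52 genes), and 0.47 for the change of association (30 genes). The 95th percentiles of these differences were, in the same order, 0.95, 1.30, 1.58, 1.23 and 1.02. A ratio of a single gene just beyond 2-fold, a log2 of 1, can therefore lie within probe error.

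Before the data were examined, 17 gene lists were fixed: fermentation and sucrose synthase, the core hypoxia response of other studies, cytosolic glycolysis, heat shock proteins, nuclear-encoded photosynthesis, cytosolic ribosomal proteins, translation factors, core histones, cell wall expansion, ethylene synthesis and signalling, sugar starvation, reactive oxygen and alternative oxidase, flavonoid synthesis, mRNAs with conserved upstream open reading frames, root markers, and the chloroplast-encoded and mitochondrion-encoded genes. Mitochondrial genes had to be recognised by symbol, a choice made after the annotation was seen. A list's median log2 ratio was placed among the medians of 10000 random lists of the same size matched on mean log2 signal in 20 bins, for lists with at least 3 measured members. This percentile describes these arrays only. No member of the flavonoid list was above the floor on any array, so it has no ratio. Of the genes written down, 22 of 46 in the core hypoxia list and 87 of 155 ribosomal protein genes had a named probe set. The counts were 5 of 16 for heat shock proteins, 10 of 55 for nuclear photosynthesis and 4 of 34 for translation factors. They were 8 of 27 for cell wall expansion, 3 of 21 for sugar starvation and 3 of 23 for reactive oxygen. For upstream open reading frames, root markers and ethylene they were 10 of 19, 3 of 15 and 2 of 19.

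Named genes followed a rule fixed in advance: the 10 highest and the 10 lowest ratios in total RNA among genes at least 2-fold the same way in large-polysome RNA, the 6 highest and 6 lowest mean large-polysome over total ratios among genes 2-fold the same way in both conditions, the 8 largest changes of association each way, up to 4 members of each list with the largest ratio and 1 that went furthest the other way, and, as bounds, the 5 brightest genes that were below the floor on 1 side. All but the bounds were above the floor on every array their ratio uses. As organelle genes filled most of the places for the change of association, the 8 nuclear genes each way were added after the data were seen.

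Results were recomputed under 10 alternatives listed before the data were examined, which changed the scaling (the deposited values, equal medians, quantile normalization), the floor (25th or 60th percentile, or none with a pseudocount equal to the floor), the fold threshold (1.5 or 3), and the choice of probe sets. A further 3 were added after seeing the data: scaling on 18 spiked bacterial and phage control probe sets, counts over all non-control probe sets, and counts over nuclear genes. The 18 probe sets were the Bio and Cre controls. Scaling on them changes a single factor per array and is not taken as a measure of how much mRNA a sample held. The procedure was tested on simulated data made from these arrays with noise of SD 0.2 on the log2 scale and 200 changed genes among 13356. The changed genes, and the shifted list below, were planted only on probe sets well above the floor. What was recovered therefore does not cover dim genes. For hypoxia over control in total RNA, 5.97% of genes planted at 1.5-fold, 94.0% of those at 3-fold and 100% of those at 4-fold passed the 2-fold threshold, as did 0.0279% of unchanged genes. The noise was a chosen SD for each array and was not estimated from these arrays. Pairs of probe sets differed here by a median of 0.33 in total RNA. That is a difference between ratios and cannot be set directly against the SD. As the noise was chosen, the share of false calls may be higher here, and it was not computed for the other comparisons. For the change of association, a list of 80 genes shifted by -0.40 was recovered with a median of -0.31, below all random lists, and 7 of 100 unshifted lists lay outside the 2.5th to 97.5th percentiles. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.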

Results

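Steady-state mRNA and mRNA on large polysomes were profiled in 7-d-old wild-type Ler seedlings kept under low light, either non-stressed or exposed to 12 h of hypoxia, to follow changes in transcript abundance and in association with large polysomes. Each of the 4 groups was measured on 1 array. Above the common floor were 59.98% of probe sets in total RNA of control seedlings, 56.4% in total RNA in hypoxia, 57.3% in large-polysome RNA of control and 54.7% in large-polysome RNA in hypoxia. The ratio of 3' to 5' signal of the actin control was 1.39 and 1.22 in total RNA of control and hypoxic seedlings, and 2.45 and 2.15 in large-polysome RNA. The same ratio for GAPDH lay between 0.958 and 1.29 on the 4 arrays, and that for ubiquitin was 1.49 and 1.04 in total RNA and 2.02 and 1.24 in large-polysome RNA. A second pair of actin control probe sets gave 5.46 and 5.53 in total RNA, and 10.9 and 7.34 in large-polysome RNA. The second GAPDH pair gave 1.06 and 0.75 in total RNA, and 1.12 and 0.80 in large-polysome RNA. The second ubiquitin pair gave 1.29 and 1.13 in total RNA, and 1.92 and 1.94 in large-polysome RNA. Directions are relative to the average signal of an array, and none has a replicate check. No sampling time is given for total RNA of control seedlings, so a difference in time may enter the ratios that use that array.

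In total RNA, hypoxic seedlings carried far more mRNA of the core hypoxia response and of small heat shock proteins than control seedlings, and less mRNA for cell wall expansion. Pyruvate decarboxylase PDC2, an enzyme of ethanol fermentation, was 8.89-fold higher, and AT4G10270, a member of the core list, had the highest ratio of the genes above the floor on all 4 arrays, at 22.7-fold. GSTU25, a glutathione S-transferase, was 17.3-fold higher, and AT1G54050, which encodes a small heat shock protein, 15.6-fold higher. XTH16, a xyloglucan endotransglucosylase/hydrolase that remodels the cell wall, had a log2 ratio of -2.60.

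Of the 46 genes written down for the core hypoxia list, 22 had a named probe set and 21 were measured. All 21 were at least 2-fold higher in total RNA in hypoxia. Their median log2 ratio was 2.67, above all 10000 matched random lists. As the list was drawn from the hypoxia response in other studies, this rise serves as a check of the arrays. Besides AT4G10270 with a log2 ratio of 4.51, the calmodulin-like gene CML38 stood at 4.26, AT1G33055 at 3.66 and AT3G27220 at 3.30. AT5G10040, whose control signal was below the floor, was at least 34.1-fold higher, and AT3G10040 at least 19.5-fold higher. Of the 9 genes written down for fermentation and sucrose synthase only 2 had a named probe set, PDC2 at 3.15 and the lactate dehydrogenase gene AT4G17260 at 1.71. Of the 26 genes written down for cytosolic glycolysis only 7 had a named probe set and 6 were measured, so the values cover a small part of the pathway. These 6 had a median of 0.38, at percentile 84.06 of random lists, with 5 above 0 and none at 2-fold. The highest of them was the pyruvate kinase gene AT5G08570 at 0.70, GAPC2 stood at 0.29, and the lowest was AT5G56350 at -0.28.

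All 5 measured heat shock protein genes were at least 2-fold higher, with a median log2 ratio of 2.96, above all matched random lists. AT1G53540 had 4.29, AT2G29500 3.40, ATHSP22.0 2.96 and AT5G51440 2.91. Of the 23 genes written down for reactive oxygen and alternative oxidase only 3 had a named probe set, none an alternative oxidase. These were GSTU25, the zinc finger gene STZ and AT2G21640, with ratios of 4.11, 2.54 and 1.80. Other genes among the 10 highest were AT2G41730 at 3.47, AT1G19020 at 3.41 and the core hypoxia member AT2G17850 at 3.15. From below the floor in control, AT1G63540, AT2G32020 and the plant defensin gene PDF1.4 were at least 14.2-, 12.4- and 10.6-fold higher.

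The cell wall expansion list had a median of -0.60 over 8 genes in total RNA, at percentile 0.93 of random lists, with 3 members at least 2-fold lower. XTH19 stood at -2.57 and the expansin genes EXPA8 and EXPA4 at -1.04 and -0.79, while EXPA9 went the other way at 0.32. The lowest ratio among genes above the floor on all 4 arrays was that of AT4G25260, a pectin methylesterase inhibitor gene, at -3.39. It was followed by AT5G10770 at -3.28, which was not lower in large-polysome RNA, and by the acyltransferase family genes AT5G01210 at -3.07, BAT1, which acts on brassinosteroids, at -2.88 and AT5G47980 at -2.66. AT5G59540 stood at -2.65, the vacuolar invertase gene AT1G62660 at -2.61, AT3G49220 at -2.60, AT5G57785 at -2.59 and AT4G18970 at -2.58. Below the floor in hypoxia, AT3G54400 was at least 26.5-fold lower, AT5G19890 at least 17.1-fold lower, AT5G62280 10.7-fold, AT5G57760 10.2-fold and AT5G04960 9.58-fold.

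The 3 root markers also had low ratios in total RNA, with a median of -1.29, at percentile 0.16. EXPA18 stood at -1.82 and PYK10, a root beta-glucosidase, at -0.44. Of the 26 core histone genes written down only 5 had a named probe set, all of them histone H2B (HTB) genes. All 5 were below 0, with a median of -0.58, at percentile 10.45, and HTB2 at -0.75. Sugar starvation genes were mixed, with MCCA at 0.67, IVD at 0.64 and ATL8 at -1.60, and a median of 0.64. EIN3, a transcription factor of ethylene signalling, stood at 0.40 and RTE1 at -0.51.

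Scaling on the spiked controls shifts the median of all genes in total RNA by 0.28, and this common shift alone can turn the sign of a list median near 0. The median of the upstream open reading frame list moved by more than that shift, and relative to all genes it was -0.36 on the main scaling. The medians of ribosomal proteins (percentile 0.22) and chloroplast-encoded genes (percentile 0) lay low among random lists. The medians went from -0.09 to 0.21 for 85 ribosomal protein genes, from -0.10 to 0.20 for 10 nuclear photosynthesis genes, from -0.20 to 0.10 for 4 translation factors, from -0.42 to 0.03 for 9 genes with conserved upstream open reading frames and from -0.27 to 0.03 for 69 chloroplast-encoded genes; relative to all genes on that scale they were -0.01, -0.02, -0.12, -0.20 and -0.19. Among genes above the floor in total RNA in both conditions, the largest ratios in these lists were -0.97 for the ribosomal protein gene AT4G30800, -0.59 for LHCB4.3, -0.36 for EIF4A-2, -1.51 for AT5G15950 and 2.97 for petD. Among the mitochondrial genes 9 were measured, with a median of 0.55 that became -0.52 with the floor at the 60th percentile, cox1 at 1.45 and nad4 at -0.95.

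Counted over named genes, 413 of 7636 were at least 2-fold higher in total RNA and 668 at least 2-fold lower. Quantile normalization, which shifted the median of all genes by 0.11, gave a more even split of 540 higher and 580 lower, and scaling on the spiked controls, which shifted it by 0.28, gave 787 and 309. Over all 14345 measured probe sets, named or not, the counts were 775 and 1440.

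In large-polysome RNA the same groups stood out in hypoxia, and ribosomal protein mRNAs were lower. The core hypoxia list had a median log2 ratio of 3.38 with all 21 measured members at least 2-fold higher, and the 5 heat shock genes had 3.50, with all 5 at least 2-fold higher. Cytosolic ribosomal proteins had a median of -0.51 over 86 genes, of which 83 were below 0 and 12 at least 2-fold lower, below all 10000 matched random lists. PDC2 was 14.6-fold higher and AT1G54050 28.5-fold higher.

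Among core hypoxia genes, AT4G10270 was 15.9-fold higher in large-polysome RNA and PDC2 had a log2 ratio of 3.87, AT2G17850 at 3.79, AT1G33055 at 3.75 and AT3G27220 at 3.38. AT5G10040 was at least 41.7-fold and CML38 at least 33.4-fold higher, both from below the floor. The heat shock genes AT1G53540 and ATHSP22.0 were at least 42.1-fold and 17.5-fold higher, AT2G29500 stood at 3.28 and AT5G51440 was 4.91-fold higher. GSTU25 stood at 4.63, STZ at 2.09 and AT2G21640 at 1.94. Other genes that led in total RNA stood at 4.83 for AT1G54050, 3.89 for AT1G19020 and 3.33 for AT2G41730, and AT2G32020 was at least 15.6-fold higher. The lactate dehydrogenase gene AT4G17260 was 3.99-fold higher. The 6 glycolysis genes had a median of 0.52, led by AT5G63680 at 0.83.

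The lowest ribosomal protein genes above the floor on both large-polysome arrays were AT3G11250 at -1.77, AT5G39850 at -1.51, AT5G02610 at -1.49 and AT5G67510 at -1.39, and the highest was AT5G20290 at 0.33. The cell wall expansion list had a median of -1.38 over 7 genes, 5 of them at least 2-fold lower, at percentile 0.01, with XTH16 at -2.44, XTH19 at -1.55, EXPA9 at -1.48 and XTH18 at 0.82. Histone H2B genes had a median of -0.29, with HTB1 at -1.71. Among the genes lowest in total RNA, AT4G25260 stood at -3.01, AT4G18970 at -2.77, AT5G57785 at -2.64, AT5G01210 at -2.35, AT5G47980 and AT3G49220 at -2.32, AT5G59540 at -2.10, BAT1 at -1.77 and AT1G62660 at -1.39. AT5G62280 and the protein kinase gene WAG2 were at least 8.68-fold and 7.10-fold lower, and AT4G35720, AT3G28040 and AT5G57760 at least 6.63-, 6.56- and 6.45-fold lower.

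Chloroplast-encoded genes had a median of 0.53 over 69 genes in large-polysome RNA, above all random lists, with 19 at least 2-fold higher and 6 at least 2-fold lower. Mitochondrial genes had a median of 0.85 over 7 genes, with ccb382 at 1.80 and cox1 at 1.12. Sugar starvation genes had a median of 1.03, with MCCA at 1.90 and ATL8 at -1.36. EIN3 stood at 0.11 and RTE1 at -0.81. The 4 translation factors had a median of -0.31, with EIF4A-2 at -0.81 and AT5G12110 at 0.37. Root markers had a median of -0.21, with EXPA18 at -1.15 and PYK10 at 0.16. The sign depended on the scaling for nuclear photosynthesis, with a median of 0.02 that became -0.11 after quantile normalization and -0.34 with the spiked controls, and for the upstream open reading frame list, 0.16 against -0.20 with the spiked controls, where the 2 medians were 0.05 and 0.19 above all genes. Their largest members were ATPC1 at -0.41 and AT5G15950 at -1.82.

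In all, 588 of 7312 genes were at least 2-fold higher and 737 at least 2-fold lower in large-polysome RNA. Scaling on the spiked controls, which shifted the median of all genes by -0.31, gave 315 higher and 1472 lower. Over all 13801 measured probe sets the counts were 1122 and 1543.

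The responses in the 2 fractions, which share no array, ran closely together for nuclear genes and opposite for chloroplast genes. Across 5842 genes above the floor on all arrays, Pearson r between the log2 ratios was 0.773 and Spearman rho 0.730. Genes are not independent replicates, so no p is given. At least 2-fold higher in both fractions were 278 genes and lower in both 397, against 34.3 and 68.1 if the calls had been independent among the 7052 genes measured in both. For 5771 nuclear genes r was 0.799, and for 66 chloroplast-encoded genes it was -0.680. Of the 9 genes at least 2-fold in opposite directions, 8 were chloroplast-encoded.

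**Figure D1:**
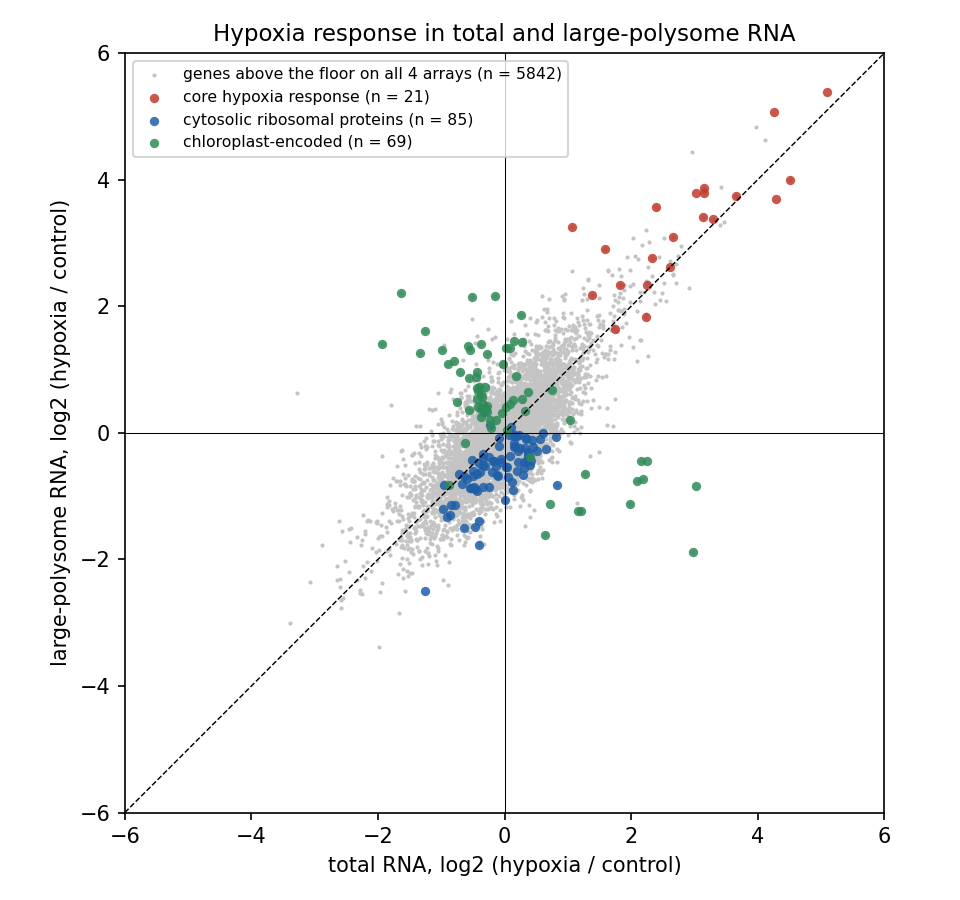
Log2 ratio of hypoxia over control in total RNA (x axis) and in large-polysome RNA (y axis); grey points are the 5842 genes above the floor on all 4 arrays, coloured points are members of 3 lists, entered at their bound where 1 side was below the floor, and the dashed line marks equal ratios. All 21 measured core hypoxia genes lie above 1 on both axes. Ribosomal proteins have medians of -0.09 on the x axis, 0.21 when scaled on the spiked controls, and -0.51 on the y axis. Chloroplast-encoded genes run against the diagonal with r -0.680 over 66 genes.

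In control seedlings, large-polysome RNA was rich in ribosomal protein and histone H2B mRNAs compared with total RNA. The median log2 ratio of large-polysome over total RNA was 0.52 for 86 ribosomal protein genes, with 83 above 0 and 14 at least 2-fold higher, above all random lists. It was 0.76 for 5 histone genes, all above 0. The highest ribosomal protein genes above the floor in both fractions were AT5G39850 at 1.38, AT3G52580 at 1.26 and AT2G32220 at 1.24, and AT5G20290 was lowest at -0.19. HTB1 stood at 1.29, HTB4 at 0.82 and HTB11 at 0.66.

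In control, chloroplast-encoded genes had a median of -0.40 against 0.27 with the spiked controls, a wide spread with 9 of 69 genes at least 2-fold higher and 13 lower, psbA at -3.42 and petD at 2.53. Reactive oxygen genes had a median of 0.85, with AT2G21640 at 0.86, and translation factors 0.35, with AT5G12110 at 0.58. The 4 measured heat shock genes had a median of 0.15, with AT5G51440 at 1.08. The 2 ethylene genes had 0.16, with RTE1 at 0.34 and EIN3 at -0.01. Sugar starvation genes had -0.74, with MCCA at -1.09. The core hypoxia list lay at the average gene, with a median of -0.01 over 18 genes, from AT1G19530 at -0.56 to AT4G10270 at 0.82. Several other medians came to about 0 or turned sign on the spiked controls, where all genes shifted by 0.62: root markers went from -0.67 to 0.00, mitochondrial genes from -0.52 to 0.15, the upstream open reading frame list from -0.19 to 0.51, glycolysis from -0.14 to 0.53 and the core hypoxia list to 0.64, while relative to all genes they were -0.59, -0.44, -0.09, -0.06 and 0.05. After quantile normalization cell wall expansion went from 0.03 to -0.03. Nuclear photosynthesis genes had 0.09, with LHCB4.2 at -0.72.

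In hypoxia, histone H2B mRNAs had the highest large-polysome over total ratio of the lists, with a median of 1.05 over 5 genes, 3 of them at least 2-fold higher and HTB2 at 1.18. Heat shock genes had 0.70, with all 5 above 0 and AT5G37670 at 1.43. The core hypoxia list had 0.30 over 21 genes, at percentile 99.28, led by AT3G10020 at 1.66, with AT3G10040 lowest at -0.59. Ribosomal protein genes had 0.08 over 84 genes, from AT1G26880 at 0.82 to AT3G02080 at -0.53, and none at 2-fold.

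Other lists in hypoxia had medians of 0.47 for reactive oxygen genes (GSTU25 at 0.47), 0.24 for chloroplast-encoded genes (rps14 at -2.97 and rpoB at -2.22), -0.34 for mitochondrial genes (1.01 with the floor at the 60th percentile; nad4 at 1.39), 0.16 for cell wall expansion (EXPA9 at -0.62), 0.15 for sugar starvation (IVD at -0.35), 0.10 for translation factors (AT5G12110 at 1.09), 0.08 for glycolysis (AT5G56350 at 0.21), -0.08 for upstream open reading frames (AT1G70780 at 0.65) and -0.03 for nuclear photosynthesis (LHCB4.3 at 0.46). For nuclear genes the fraction ratios in control and in hypoxia had r 0.434 across 5771 genes.

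The genes with the highest ratio in both conditions were AT5G01870, with 1.69 in control and 1.12 in hypoxia, AT1G62500 with 1.69 and 1.09, AT5G18600 with 1.58 and 1.09, AT2G41090 with 1.22 and 1.23, AT1G29250 with 1.29 and 1.03, and AT1G71430 with 1.12 and 1.18. The lowest were DI19, with -2.04 and -1.58, AT5G47435 with -1.65 and -1.60, AT5G41940 with -1.89 and -1.19, AT3G60300 with -1.93 and -1.07, AT3G18215 with -1.57 and -1.38, and AT5G16110 with -1.66 and -1.27. At least 2-fold higher in large-polysome RNA were 156 of 7507 genes in control and 74 of 7077 in hypoxia, and lower were 208 and 77. The actin control's 3' to 5' ratio was higher in both large-polysome arrays, at 2.45 and 2.15, than in total RNA, at 1.39 and 1.22. Scaling on the spiked controls shifted the median of all genes by 0.62 in control, which gave 1517 genes higher and 20 lower, and by 0.01 in hypoxia.

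**Figure D2:**
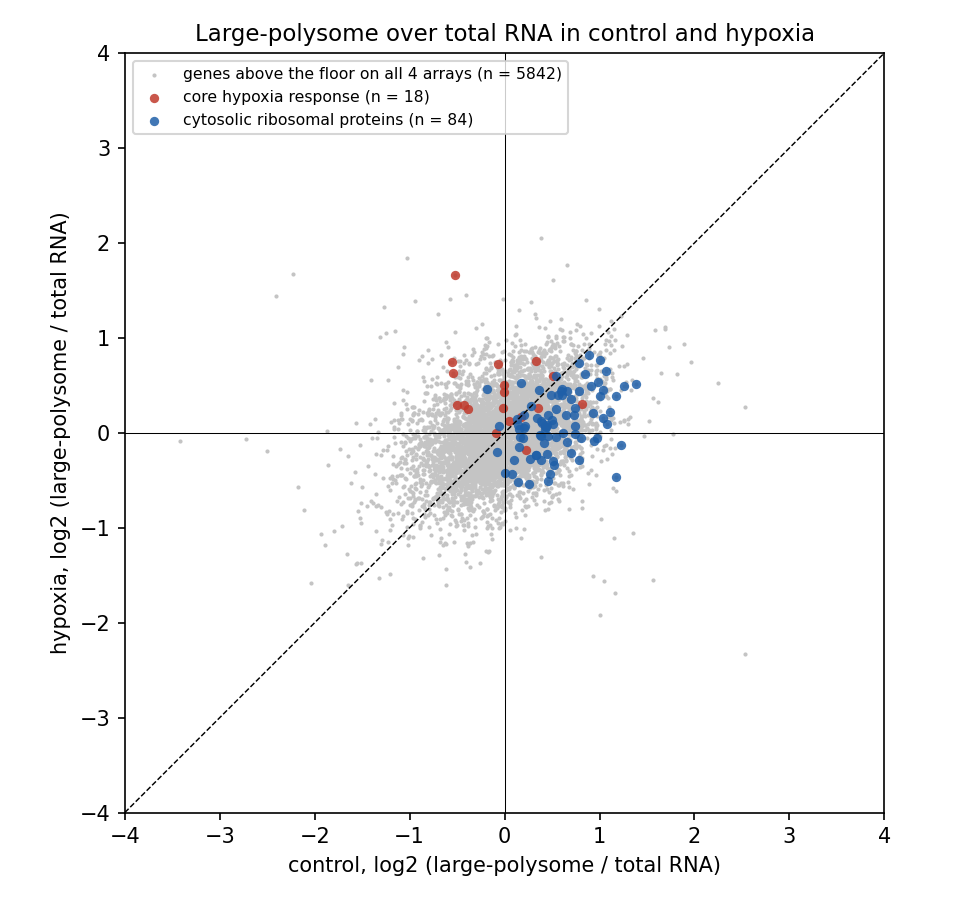
Log2 ratio of large-polysome over total RNA in control (x axis) and in hypoxia (y axis); grey points are the 5842 genes above the floor on all 4 arrays and the dashed line marks equal ratios. Ribosomal protein genes (blue) lie mostly right of 0 in control, with a median of 0.52 over 86 genes, and around 0.08 over 84 genes in hypoxia, while core hypoxia genes (red) lie around -0.01 in control (0.64 when scaled on the spiked controls) and 0.30 in hypoxia.

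The change of association in hypoxia set ribosomal protein mRNAs apart from core hypoxia mRNAs. Ribosomal protein genes had a median change of -0.42 over 84 genes, with 77 below 0 and 5 at least 2-fold lower, below all 10000 random lists. Core hypoxia genes had a median of 0.43 over 17 genes, at percentile 99.97, with 13 above 0 and 3 at least 2-fold higher, but -0.24 when scaled on the spiked controls, where the median of all genes shifted by -0.65. AT3G11250 was at -1.36 and AT5G15520 at -1.64 among the first group, and AT3G10020 at 2.18, AT1G19530 at 1.31 and AT3G23170 at 1.17 in the other.

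Of the ribosomal protein genes AT5G52650 stood at -1.08 and AT5G02610 at -1.03, and AT5G20290 was highest at 0.65. Of the core hypoxia genes AT4G17670 stood at 0.79 and PDC2 at 0.72, and AT4G10270 was lowest at -0.51. The list median of ribosomal proteins was furthest from 0 in the 2 ratios that use the large-polysome control array, 0.52 in control and -0.51 in large-polysome RNA, and lay at -0.09 (percentile 0.22) and 0.08 in the 2 ratios that do not.

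Chloroplast-encoded genes spread widely in their change of association, with a median of 0.81 over 66 genes (all genes shift by -0.65 on the spiked controls), 28 at least 2-fold higher and 9 lower. The change was 3.85 for atpF, 3.34 for psbA, 2.86 for rpoC2, 2.66 for psaA and 2.59 for atpA, and -4.86 for petD, -3.11 for ndhG, -2.92 for ycf3, -2.85 for petN, -2.60 for atpI, -2.44 for petG, -2.40 for ccsA and -2.26 for rps16. The mitochondrial genes nad4 and ccb382 had 2.34 and 2.32. The largest nuclear changes were 3.90 for AT5G10770, 2.22 for AT4G13580, 2.18 for AT3G10020, 1.96 for the peroxidase gene AT5G66390, 1.89 for AT1G60200 and AT1G23120, 1.82 for AT5G09480 and 1.69 for AT2G39400. At the other end were AT5G55450 at -2.26, EXPA9 and AT3G16660 at -1.79, AT5G56940 at -1.73 and AT3G16670 at -1.72. AT4G01810 stood at -1.68, the ribosomal protein gene AT5G15520 at -1.64 and AT4G39550 at -1.61. The EXPA9 signal in large-polysome RNA in hypoxia, 140.7, was only just above the floor.

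Translation factors had a median change of -0.25, with AT5G19510 at -0.61, and the 2 measured heat shock genes, AT5G51440 and AT2G29500, had -0.62 and -0.12. The 2 ethylene genes RTE1 and EIN3 had -0.30 and -0.29. Other list medians turned sign with the common shift of all genes by -0.65 on the spiked controls: glycolysis went from 0.21 to -0.45, nuclear photosynthesis from 0.15 to -0.52, cell wall expansion from 0.16 to -0.42, sugar starvation from 0.39 to -0.28, reactive oxygen genes from 0.14 to -0.53, upstream open reading frames from 0.09 to -0.58 and mitochondrial genes from 0.03 to -0.64. Relative to all genes on that scale they were 0.21, 0.15, 0.24, 0.38, 0.14, 0.08 and 0.03. The histone median went from -0.03 to 0.01 after quantile normalization. In the nuclear lists among these, the members with the largest change were MCCA at 1.24 and XTH18 at 1.03, besides EXPA9.

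At least 2-fold higher association in hypoxia was measured for 177 of 5842 genes and lower for 111. Without organelle genes the counts were 147 and 102 of 5771. Scaling on the spiked controls gave 23 and 1240. The change of association adds the errors of all 4 arrays.

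**Figure D3:**
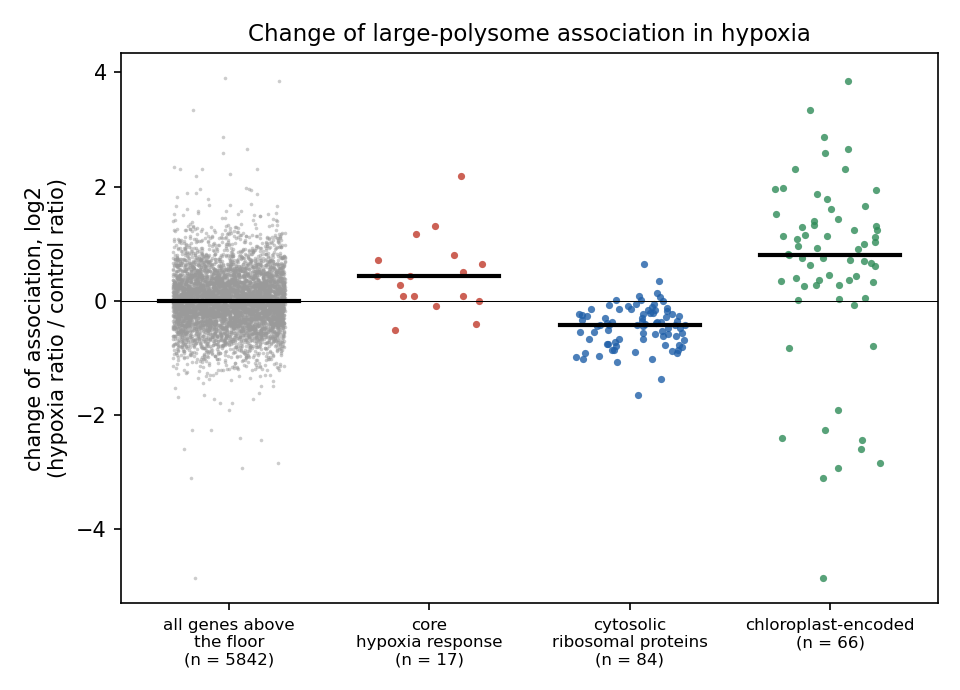
Change of large-polysome association in hypoxia (y axis, log2 of the large-polysome over total ratio in hypoxia divided by that in control) for the 5842 genes above the floor on all 4 arrays and for 3 lists; each point is a gene and the bars are medians. Medians are 0.43 for core hypoxia genes (-0.24 when scaled on the spiked controls), -0.42 for ribosomal proteins and 0.81 for chloroplast-encoded genes, which spread from -4.86 to 3.85. Scaling on the spiked controls shifts the median of all genes by -0.65.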

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

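The tests of RNA integrity, of shuffled chloroplast pairs, of swapped arrays, of priming, of the brighter core hypoxia members and of the core hypoxia change set against 0 were chosen only after the results they bear on had been seen, as was scaling on the spiked controls; the other tests were written beforehand. With 1 array per group, the differences between fractions given here were not tested, and a difference in sampling time of the total RNA control, for which no time is given, stays open for each of them.

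Chloroplast-encoded genes went opposite ways in the 2 fractions relative to the average gene, with a median log2 ratio of hypoxia over control of -0.27 in total RNA and 0.53 in large-polysome RNA; scaled on the spiked controls both were above 0, at 0.03 and 0.16, and relative to all genes -0.19 and 0.55. Higher in total and lower in large-polysome RNA were petD (2.97 and -1.88), which encodes a subunit of the cytochrome b6f complex, ndhG (1.99 and -1.12), petG (1.2 and -1.23) and ccsA (1.16 and -1.24). Lower in total and higher in large-polysome RNA were rpoC2 (-1.26 and 1.61), which encodes a subunit of the plastid RNA polymerase, the ATP synthase genes atpF (-1.64 and 2.21) and atpA (-1.34 and 1.26), and psbA (-1.94 and 1.4), the gene of the D1 protein of photosystem II. The nuclear gene AT5G55450 had 1.15 in total and -1.11 in large-polysome RNA. It is the 1 nuclear gene at least 2-fold in opposite directions.

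For the chloroplast pattern, a swap of the arrays of total and large-polysome RNA within a condition is argued against by the fraction ratios of nuclear genes, which had r 0.434 between control and hypoxia where a swap predicts a value below 0. A swap of control and hypoxia arrays within a fraction is argued against by the core hypoxia list, whose lower median was 2.67. Noise of dim probe sets would pair the 2 ratios at random, since they share no array, and is argued against as the whole cause by r -0.680 over 66 genes, below the lowest of 10000 shuffles within bins of brightness, -0.617; r among the 34 brighter genes, -0.32, lay between the bounds set for it and decides nothing. A difference in how RNA without a long poly(A) tail was primed stays open too, because 7 mitochondrial genes are too few for their r of -0.416 to decide. For petD, intensities were 161.7 in total control and 253.2 in large-polysome hypoxia, against 1270.5 in total hypoxia and 934.5 in large-polysome control. For atpF they were, in that order, 4112.8 and 3590.3 against 1320.7 and 773.5. The psbA values, 5289.1 and 1304.7 against 1382.2 and 494.4, did not pair this way. A difference in sample preparation that set total control and large-polysome hypoxia apart was not tested and stays open. Chloroplast mRNAs are translated on the organelle's own ribosomes, and an effect of hypoxia on them remains an untested hypothesis.

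Ribosomal protein mRNAs lay lower on large polysomes in hypoxia than in control, with a median change of -0.42. Their brightness does not account for it, as the median lay at percentile 0 of lists matched on signal, nor does an intensity-dependent scaling, as the median stayed at -0.41 or below against all genes; a single factor per array cancels in that value, so quantile normalization was the informative setting. RNA integrity cannot be told apart from hypoxia here, since the change of the 3' to 5' ratio had a median of -0.009 over 3 control genes, none of them in the list, and -0.008 over 6 pairs of control probe sets, of which the second actin pair had -0.59. A property of the large-polysome control sample stays open as well, because the list medians were 0.52 and -0.51 in the 2 ratios that use that array against -0.09 and 0.08 in the others. Lower loading of ribosomal protein mRNAs in hypoxia is a hypothesis that more samples per group would have to test.

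Core hypoxia mRNAs lay higher on large polysomes in hypoxia than in control, with a median change of 0.43. Background under dim control signals would leave the ratio within hypoxia, at percentile 99.28, as it is, so that value decides nothing, but the 8 members brighter in control than the list's median had a median change of 0.47, which argues against background in those members. An intensity-dependent scaling is argued against by the change relative to all genes, which was at least 0.34 under quantile normalization and the other scalings. A single factor per array cancels in that value apart from the floor, so quantile normalization was the informative setting. Set against 0, the change depended on the scaling and was -0.24 on the spiked controls, so only the gain relative to other mRNAs holds in these arrays. Preferential loading of these mRNAs in hypoxia is a hypothesis that more samples per group would have to test. A difference in sample preparation that set total control and large-polysome hypoxia apart from the other arrays would give the same pattern.

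Among the control probe sets, which enter none of the comparisons, the 5S ribosomal RNA signal was at least 7.14-fold higher in hypoxia in total RNA, from a signal at the floor, while the 25S ribosomal RNA signal was 1.02-fold that of control there and went from an intensity of 64.4, below the floor, to 254 in large-polysome RNA. Another Arabidopsis control probe set fell below the floor in total RNA and was at least 2.49-fold lower. Of the 5 ubiquitin control probe sets, 3 were 2.04-fold, 2.02-fold and 2.03-fold higher in large-polysome RNA in hypoxia, and the other 2 were 1.19-fold and 1.94-fold higher.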

How the results depend on the processing

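No paired analysis was possible because the labels give 1 sample per group and no replicate numbers, and for the same reason no replicate could be left out. Scaling on the spiked controls, all probe sets and nuclear genes were chosen after seeing the data; the other alternatives were planned. Of the 603 list medians recomputed over 9 settings, 548 moved by less than the median difference between probe sets of the same gene, 49 moved by more and 6 changed sign after lying outside the central 95% of random lists. Of 2798 values of named genes, 2583 moved by less, 215 by more, and none that had reached 2-fold changed sign. Deposited values, equal medians, quantile normalization, the mean of a gene's probe sets, probe sets with a plain suffix, and nuclear genes alone kept every count of genes at least 2-fold higher or lower, in 1 comparison or in both RNA fractions, within 1.5 times; genes at least 2-fold in opposite directions fell from 9 to 1 with nuclear genes alone. Signal over background limits the rest, since 5460 genes were below the floor on every array.

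A floor at the 25th percentile gave 364 genes lower in large-polysome RNA in control, 126 higher and 186 lower in hypoxia, and 296 higher and 248 lower for the change of association. A floor at the 60th percentile, with fewer genes measured, gave 301 lower in total RNA, 376 lower in large-polysome RNA, 96 higher and 104 lower for the fractions in control, 45 and 50 in hypoxia, 95 and 50 for the change of association, and 173 lower in both RNA fractions. It turned the mitochondrial medians to -0.52 in total RNA and 1.01 for the fractions in hypoxia, on fewer genes. With a pseudocount, which shrinks ratios of dim genes, the counts were 374 lower in total RNA, 465 lower in large-polysome RNA, 63 higher and 83 lower for the fractions in control, 27 and 33 in hypoxia, 58 lower for the change of association and 218 lower in both RNA fractions.

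At 3-fold there were 150 higher and 179 lower in total RNA, 209 and 206 in large-polysome RNA, 20 and 25 for the fractions in control, 6 and 7 in hypoxia, 27 and 17 for the change of association, and 115 and 91 in both RNA fractions. At 1.5-fold these were 1119 and 1551, 1267 and 1701, 751 and 885, 551 and 530, 641 and 620, and 722 and 1009. Over all probe sets, of which there are more than named genes, they were 775 and 1440, 1122 and 1543, 278 and 478, 137 and 166, 334 and 207, and 553 and 903.

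Scaling on the spiked controls gave 787 higher and 309 lower in total RNA, 315 and 1472 in large-polysome RNA, 1517 and 20 for the fractions in control, and 23 and 1240 for the change of association, because it shifts the median of all genes by 0.28, -0.31, 0.62 and -0.65. It turned the change of association of core hypoxia genes to -0.24, ribosomal proteins in total RNA to 0.21, and chloroplast-encoded genes to 0.029 in total RNA and 0.27 for the fractions in control. Why the spiked signals differ between arrays was not tested.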

Other observations

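The groups of genes described here were chosen after the data were seen. Genes that share a symbol prefix were taken as families where at least 8 members were measured, which gave 37 family medians. Of these, 4 lay outside the central 95% of random lists matched on signal, where 1.85 would by definition. In the simulated data 7 of 100 unshifted lists did, but these were random genes with independent noise, for the change of association only. The family medians are not independent, since a family can enter several comparisons that share arrays. Beta-glucosidase (BGLU) genes had a median change of association of 0.67 over 8 genes, at percentile 99.95, with BGLU19 at 1.35, BGLU46 at 1.21 and BGLU44 at -0.38; on the spiked controls the median was 0.00, which is 0.66 above all genes. UDP-glycosyltransferase (UGT) genes, which attach sugars to small molecules, had a median change of association of 0.33 over 16 genes, at percentile 99.44, and -0.30 on the spiked controls, which is 0.36 above all genes. In total RNA 28 UGT genes had a median of -0.37, at percentile 1.68. Of these, 4 were at least 2-fold higher in hypoxia, such as UGT73B4 at 2.28 and UGT87A2 at 1.83. Another 8 were at least 2-fold lower, such as UGT71C1 at -2.46 and UGT72E2 at -1.50. In large-polysome RNA 26 UGT genes had a median of -0.17, at percentile 32.11. A fall in total RNA by itself raises the change of association, so these UGT medians are not separate results. The expansins (EXPA), which overlap the cell wall and root lists, had a median of -1.08 over 8 genes in large-polysome RNA, at percentile 0.06, with EXPA20 at 0.54.

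Among probe sets with no gene name here, 252515_at had log2 ratios of hypoxia over control of 4.16 in total and 5.20 in large-polysome RNA, and 245173_at had an intensity of 172 in control and 3160 in hypoxia in total RNA and a log2 ratio of 4.59 in large-polysome RNA. At the other end, 249895_at had -4.11 and -3.30, and 245325_at had -3.51 and -3.09.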
